A study of Mus musculus with 11 samples.

How the data were processed

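RNA was measured in the whole colon wall of 11 mice, 6 Tnfr1-/- (the gene Tnfrsf1a) and 5 wild type. Per the labels' protocols, tissue was homogenised in Trizol, RNA was purified on columns, and stranded mRNA libraries were read from a single end for 75 bases on a NextSeq. The submitters' processing notes name CASAVA, kallisto, sleuth and the mouse build mm10, without versions. The labels do not state sex, litter, cage, dissection day or sequencing batch.

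The deposited table has 113991 lines for 113193 distinct transcripts. For 584 transcripts the table has more than 1 line, with the same values each time, and 1 line of each was kept. The authors' values per sample are a normalized signal: TPM divided by a size factor for each library, in the form that sleuth writes. Per the file headers, the p-value and q-value columns come from the authors' own test of each transcript. The deposited mean over samples is on the natural log (ln) scale of normalized estimated counts. The deposited fold change of the authors is a log2 ratio of group means, Tnfr1-/- over wild type.

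The table holds no read totals. Depth was estimated from the authors' deposited means, which tie abundance to transcript length by a straight line. Over 10347 transcripts that line crossed 0 at 199 bases, with a largest relative residual of 8.8e-06, as a fixed fragment length of 200 bases gives. The factor for each library was then chosen as the one that brought most low values of genes with 1 transcript within 0.02 of a whole read. At that factor 41.1% to 44.9% of the values were whole, against 2.82% to 2.97% at a typical other factor. Estimated depth ran from 27.6 to 42.1 M reads per library, and the median 95% interval of a gene reached 0.217 to each side on the log2 scale. Because most values were not whole, the depths are estimates and no count test was run as the main test.

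Values were summed over the transcripts of each Ensembl gene, giving 35683 genes. The 97 transcripts without a gene held 0.031% of the summed abundance and were left out. A gene or transcript was tested when its value was at least 1 in at least 5 libraries. Groups were compared on log2(value + 0.5) with limma 3.58.1 (empirical Bayes with a trend on the mean) in R 4.3.3. The tests were two-sided, and a call needed a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 0.5) scale, which understates changes of genes with low values. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Positions are from GENCODE M21 on GRCm38 (mm10).

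The groups, the tests, the 38 gene lists and the rule for named genes were chosen before the data were examined. That plan put a count test first if the table held counts. Since it holds normalized abundance, the branch of the plan for such values was used. A list's score in a library is the mean over its tested members of the log2 value minus the gene's mean over the 11 libraries. Group means of the score were compared by an exact permutation test over all 462 splits of the libraries into 6 and 5, two-sided, adjusted over the 36 lists with at least 5 tested members. The smallest p such a test can give is 0.0022. The list of pancreatic genes, with 4 tested members, and that of sex-linked genes, with 1, were not tested. Camera was run beside it with a preset correlation between genes of 0.01 and with an estimated one.

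Named genes are Tnfrsf1a, the 12 called genes with a mean of at least 5 and the largest change in each direction or, where fewer than 10 genes pass, the 10 with the smallest p, and up to 4 members with the smallest p of each list described. Predicted genes, pseudogenes, Xist and Y-linked genes were counted but not named under that rule. Any other gene named was chosen after its values were seen. Some genes that the rule takes are not reported here.

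The tests were checked on simulated data with the real means and spreads, in 5 simulations with 200 changed features each, all with a mean above 5. Among 15079 genes, 75.5% of 1.5-fold changes, 90.4% of 2-fold changes and 95.5% of 4-fold changes were called, and 5.33% of the calls were false. Among 33276 transcripts these shares were 46.3%, 72.5% and 93.3%, with 6.37% false. The adjustment for multiple tests is less strict with 200 changed features than with few. For data with as few calls as here, 1 gene and 3 transcripts, these shares of recovered changes are therefore upper limits. On 14904 genes the list test gave a p under 0.05 in 5.28% of lists without a change, and called 97.8% of lists whose members were all higher by 0.5. The simulated genes varied independently, which real list members do not, so the last share is an upper limit.

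Alternatives planned from the start were quantile normalization, no filter and a filter at a value of 10, pseudocounts of 1 and 0.1, columns rescaled to TPM, sample quality weights, the replicate number as a block, other list scores, and leaving out each library in turn. Added after the data were seen were the level of Eif2s3y, a Y-linked gene, as a covariate, read counts rebuilt from the estimated depth with voom, gene identifiers of 1 symbol summed, 2 residual principal components as covariates, and fits without Tnfr1-/- replicates 2 and 5 or without wild-type replicates 1 and 2. Lists of skeletal muscle, hair follicle, stratified squamous epithelium, heat shock and posterior Hox genes were also added then, as were exact permutation tests of the first 4 of these between libraries with Eif2s3y above 10 and the others. The planned Xist covariate was not run, because Xist is not among the transcripts of the table that were used.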

Results

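Gene expression was measured by RNA sequencing of mRNA from the full wall of the colon in 2-week-old mice, before weaning. The comparison was between 6 mice lacking TNFR1, the main signalling receptor for the cytokine TNF, and 5 wild-type mice. The title of the series gives the question as what deletion of the receptor does in early life. Estimated depth was 35.2 ± 3.71 M reads per Tnfr1-/- library (SD, n = 6) and 33.6 ± 5.36 M per wild-type library (SD, n = 5). In Tnfr1-/- replicates 1 to 6 it was 35.9, 29.6, 32.2, 37.7, 39.7 and 36.1 M, and in wild-type replicates 1 to 5 it was 27.6, 31.3, 32.5, 42.1 and 34.4 M. The labels state no sex, litter or batch, so litter and batch could not be set against genotype. Sex was read from the Y-linked gene Eif2s3y, which was between 54.6 and 71.5 in 2 of 6 Tnfr1-/- libraries (replicates 2 and 5) and 2 of 5 wild-type libraries (replicates 2 and 5), and at most 0.288 in the other 7. Values below are TPM scaled by a size factor for each library, called abundance here.

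Little difference in gene expression between Tnfr1-/- and wild-type colons was detected, apart from less RNA of the deleted receptor. Tnfrsf1a, which encodes TNFR1, was the 1 gene called different between the groups. Its abundance was 67.1 ± 5.04 in wild type (SD, n = 5) and 22.4 ± 3.54 in Tnfr1-/- (SD, n = 6), 33.4% of the wild-type mean. Every Tnfr1-/- library lay between 19 and 28 and every wild-type library between 61.7 and 73.1. The log2 fold change was -1.57 (SE 0.10, limma adjusted p = 8.5e-05). The gene (ENSMUSG00000030341) lies on chromosome 6 at 125349362 to 125362484 (GRCm38). RNA from the locus was thus reduced but present in all 6 Tnfr1-/- colons.

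The protein-coding transcript with 10 exons, ENSMUST00000032491.14, accounted for most of that RNA, at 55.1 ± 3.91 in wild type (SD, n = 5) and 18.6 ± 1.11 in Tnfr1-/- (SD, n = 6). It fell by 1.54 on the log2 scale (SE 0.06, limma adjusted p = 1.6e-06). A short transcript at the 5' end of the locus, ENSMUST00000131434.1, had 2 exons between 125349362 and 125350035. It was at 10.05 ± 2.07 in wild type (SD, n = 5), and in Tnfr1-/- it was listed at 0 in replicates 1, 3, 4 and 5, at 0.530 in replicate 2 and at 3.64 in replicate 6. That difference did not pass (limma adjusted p = 0.138). Of 17 other settings, 15 tested it and 2 of them called it, with limma adjusted p from 1.6e-04 (without Tnfr1-/- replicate 6) to 0.56. Both settings that called it take Tnfr1-/- replicate 6, the highest Tnfr1-/- library, out of the comparison. A transcript with a retained intron near the 3' end, ENSMUST00000134803.1, was at 0.931 ± 0.791 in wild type (SD, n = 5) and 2.15 ± 1.44 in Tnfr1-/- (SD, n = 6), and did not pass either (limma adjusted p = 0.75). Reads of 75 bases from 1 end leave the split among overlapping transcripts uncertain.

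**Figure D1:**
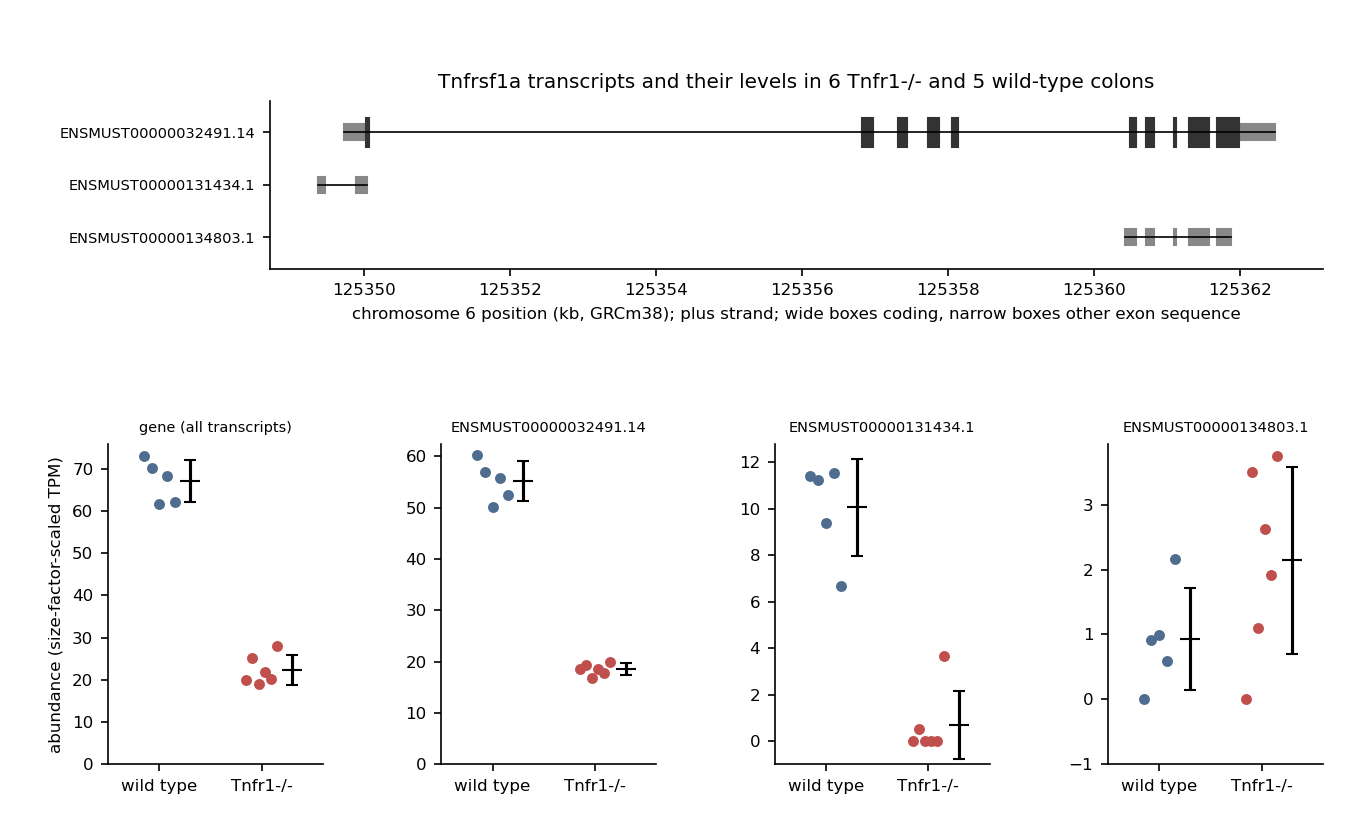
Top, exons of 3 Tnfrsf1a transcripts on chromosome 6 (kb, GRCm38). Bottom, abundance of the gene and of each transcript in every library as points, with group means and SD as bars; the gene is between 19 and 28 in the 6 Tnfr1-/- libraries and between 61.7 and 73.1 in the 5 wild-type libraries.

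Beyond Tnfrsf1a, no gene of the 15079 tested passed at an adjusted p under 0.05, and 2 genes, Tnfrsf1a among them, passed at 0.1. At an unadjusted p under 0.05 limma had 1413 genes, 634 higher and 779 lower in Tnfr1-/-, or 9.37% of those tested. Groups did not overlap at all for 109 genes higher and 116 lower, or 1.49% of genes against 0.433% by chance. The fit bounded most differences: the 95% interval of the fold change lay inside 2-fold either way for 14060 genes (93.2%) and inside 1.5-fold for 12407 (82.3%).

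The 9 genes that followed Tnfrsf1a in order of p did not pass, though for each of them the groups did not overlap. Nearest to the threshold was Bid, which encodes a BH3-only protein that links death receptors to mitochondrial apoptosis. Bid (ENSMUSG00000004446, chromosome 6, 120891930 to 120916853) was at 11.1 ± 1.53 in wild type (SD, n = 5) and 6.84 ± 0.407 in Tnfr1-/- (SD, n = 6). Its log2 fold change was -0.65 (SE 0.08, limma adjusted p = 0.057), and it lies 4.43 Mb from Tnfrsf1a. Across 24 other settings the adjusted p of Bid ranged from 0.023 to 0.41, and 4 of them called it. C2cd4b was at 4.14 ± 0.907 in wild type and 1.90 ± 0.361 in Tnfr1-/- (limma adjusted p = 0.144). Also lower in Tnfr1-/- were Hdhd3 (27.2 ± 3.72 and 19.1 ± 1.22), Itpka, an inositol trisphosphate kinase (8.32 ± 1.09 and 5.75 ± 0.387), and Aqp11, an aquaporin (11.7 ± 1.12 and 8.69 ± 0.50). Higher in Tnfr1-/- were Rbm12b2 (7.79 ± 0.645 and 11.4 ± 1.21), Ppp1r10, a regulatory subunit of protein phosphatase 1 (20.2 ± 1.63 and 25.6 ± 1.10), Hinfp, a transcription factor of histone H4 genes (6.15 ± 0.244 and 8.91 ± 1.27), and Tob2 (14.8 ± 1.55 and 20.05 ± 1.57). Adjusted p for these 7 genes ran from 0.194 to 0.206.

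At the level of single transcripts, 3 of 33276 passed, 1 lower and 2 higher in Tnfr1-/-, with 2749 at an unadjusted p under 0.05. The lower one was ENSMUST00000032491.14 of Tnfrsf1a. The higher ones, outside the rule for named genes and chosen after their values were seen, were minor isoforms. ENSMUST00000144526.1 of Midn was at 2.13 ± 0.756 in Tnfr1-/- (SD, n = 6) and above 0 in 1 of 5 wild-type libraries, at 0.116 (limma adjusted p = 0.0116). ENSMUST00000122148.7 of Bahcc1 was at 1.68 ± 0.501 in Tnfr1-/- (SD, n = 6) and 0.0741 ± 0.0600 in wild type (SD, n = 5, limma adjusted p = 0.0133). Both calls depended on the setting. Of 17 other settings, 15 tested the Midn transcript and 10 of them called it, while 10 tested the Bahcc1 transcript, which lies near the floor, and 6 of them called it. As whole genes neither differed detectably: Midn was at 49.5 ± 4.29 in wild type and 51.1 ± 2.73 in Tnfr1-/-, and Bahcc1 at 5.79 ± 0.523 and 6.23 ± 0.653. Next in order was ENSMUST00000148900.7 of Rsrp1, at 51.1 ± 7.49 in wild type and 26.4 ± 3.83 in Tnfr1-/- (limma adjusted p = 0.057). The authors' own deposited test of 49810 transcripts had 1 at a q under 0.05, the same Tnfrsf1a transcript (log2 fold change -1.57, q = 1.0e-06), 2 at a q under 0.1 and 2185 at a p under 0.05. Between 1 and 10 transcripts passed when single libraries were left out, with 1 left without Tnfr1-/- replicate 3, Tnfr1-/- replicate 5 or wild-type replicate 1, 6 without wild-type replicate 4 or 5, and 10 without wild-type replicate 2.

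None of the 36 gene lists passed the test between genotypes. The exact permutation test called 0 lists, with 0 at an unadjusted p under 0.05 and a smallest exact p of 0.0887. Camera called 10 lists with the preset correlation, all lower in Tnfr1-/-, and 0 with an estimated one, where the smallest adjusted p = 0.893. Score differences ran from -0.46 for interferon-gamma genes to 0.24 for neutrophil genes. Of 692 list members, 0 were called over all genes, and 9 were called when adjusted over the list alone. Among them were Tnfrsf25, Fadd, Ltbr, Cdx2, Myc, Nsdhl, Hspa1a and Hspa1b, of which Nsdhl, a sterol synthesis gene (29.0 ± 2.17 in wild type and 24.2 ± 1.34 in Tnfr1-/-), was named after its values were seen.

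**Figure D2:**
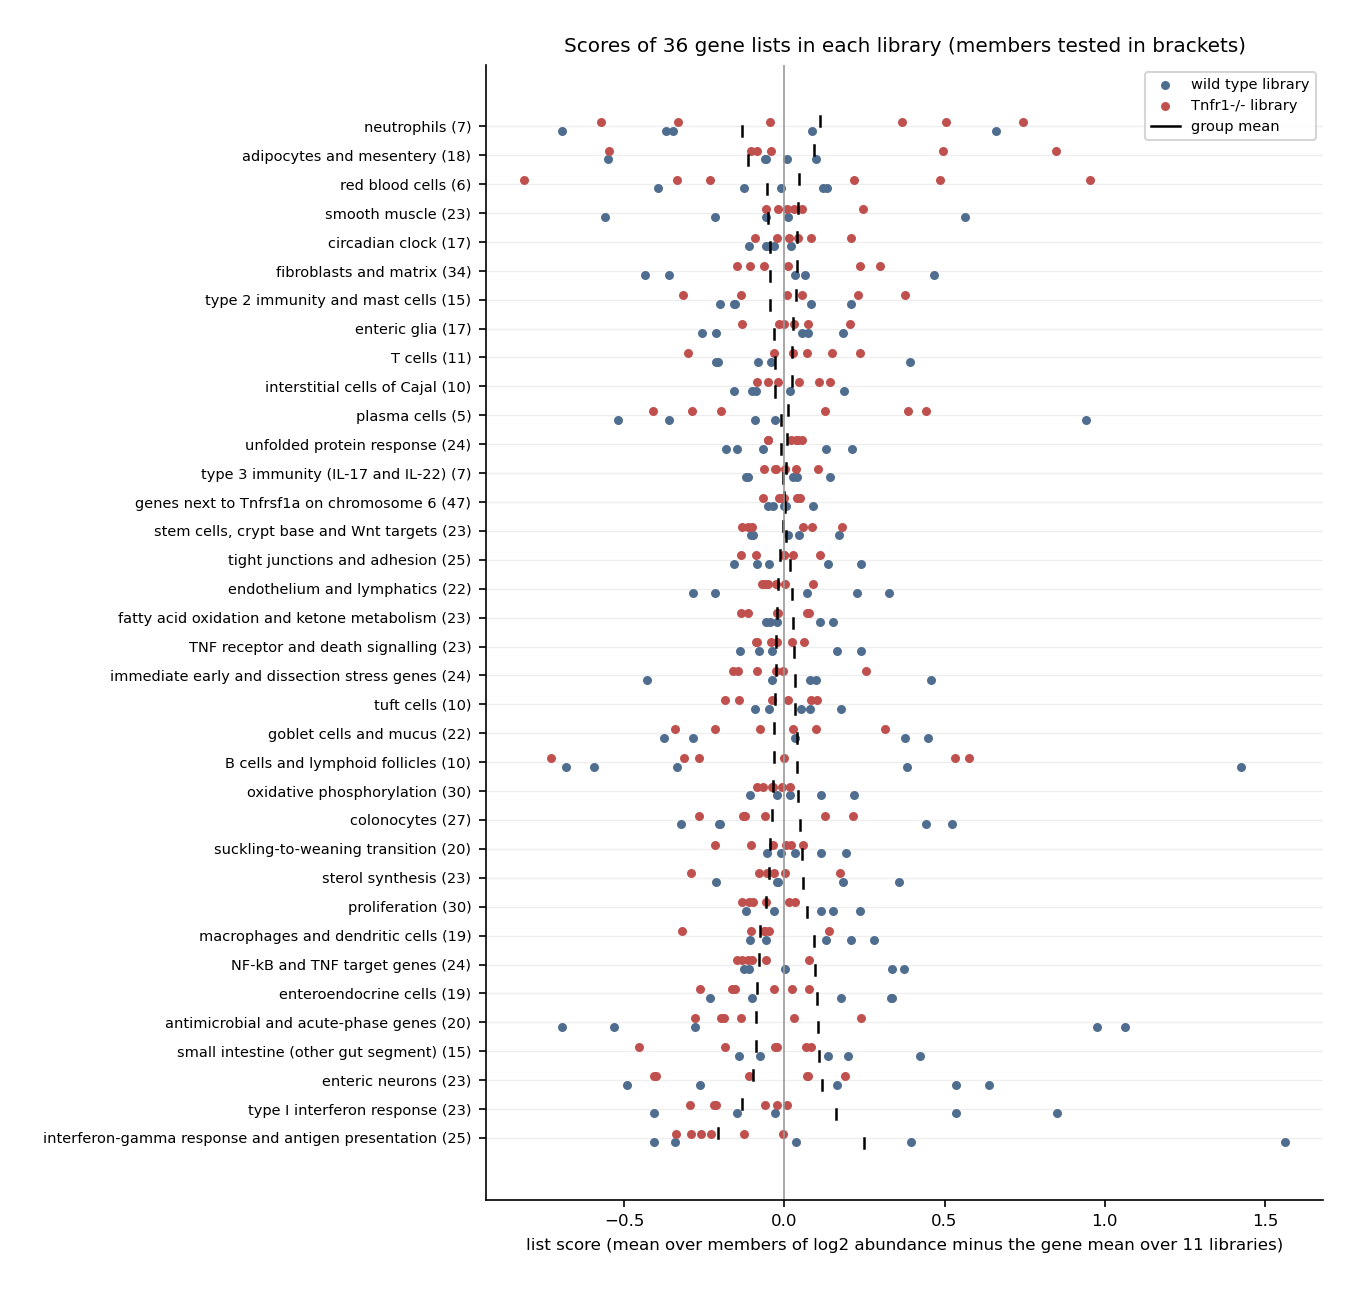
Score of each of 36 gene lists in every library, as log2 abundance relative to the mean of the 11 libraries, with points for libraries and bars for group means. Wild-type replicate 1 reaches 1.56 for interferon-gamma genes, and both wild-type replicates 1 and 2 stand at 0.976 or above for antimicrobial genes.

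Genes that TNF induces through NF-kB did not pass as a group (score difference -0.17, exact p = 0.154, adjusted p = 0.779). Of 24 members 20 were lower, 2 of them at an unadjusted p under 0.05. Saa3, an acute-phase protein, was at 11.3 ± 4.73 in wild type and 5.58 ± 0.731 in Tnfr1-/-, the monocyte chemokine Ccl2 at 1.38 ± 0.365 and 0.764 ± 0.370, and the cytokine Il1b at 1.74 ± 1.57 and 0.705 ± 0.270. The score was 0.335 and 0.375 in wild-type replicates 1 and 2 and at most 0.075 elsewhere, and without these 2 libraries the difference turned to 0.038. Leaving out the highest wild-type libraries raises a difference by construction, here and for the lists below. Genes of TNF receptor and death signalling differed by -0.06 (exact p = 0.459), with 14 of 23 lower, and by 0.060 without the same 2 libraries. When adjusted over the list alone, 3 members were called: Tnfrsf25, a death receptor of the same family (1.33 ± 0.420 in wild type and 2.69 ± 0.613 in Tnfr1-/-), Fadd, the adaptor of death receptors (7.70 ± 0.611 and 6.42 ± 0.305), and Ltbr, the lymphotoxin receptor (76.0 ± 2.21 and 69.2 ± 2.97). None of the 3 passed over all genes.

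Interferon genes and antimicrobial genes did not pass and were highest in a pair of wild-type colons. All 23 type I interferon genes were lower in Tnfr1-/- (-0.29, exact p = 0.255), as were 24 of 25 interferon-gamma and antigen presentation genes (-0.46, exact p = 0.182), with 1 of each list at an unadjusted p under 0.05. Isg15 was at 12.4 ± 10.2 in wild type and 5.66 ± 1.49 in Tnfr1-/-, Bst2 at 29.3 ± 9.59 and 20.8 ± 1.15, and H2-Ab1, an MHC class II gene, at 57.8 ± 10.8 and 45.6 ± 5.89. The interferon-gamma score was 1.56 in wild-type replicate 1 and 0.396 in replicate 2, against at most 0.036 in the other 9 libraries. Antimicrobial and acute-phase genes differed by -0.19 (exact p = 0.561), with 10 of 20 lower. The antimicrobial lectin Reg3g was at 243 and 143 in wild-type replicates 1 and 2 and between 4.90 and 41.3 elsewhere. Its relative Reg3b was at 1176 and 664 in those libraries and between 55.8 and 270 elsewhere. In replicates 1 and 2 the goblet cell score was 0.376 and 0.449, against at most 0.313 elsewhere, and the fibroblast score -0.360 and -0.435, against -0.147 or more elsewhere. Without these 2 colons the difference of the antimicrobial score turned to 0.41, that of interferon-gamma genes to 0.026 and that of type I interferon genes to 0.074. These 2 were picked for their high scores. Leaving them out raises each difference by construction, so the turns do not bear on a cause.

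**Figure D3:**
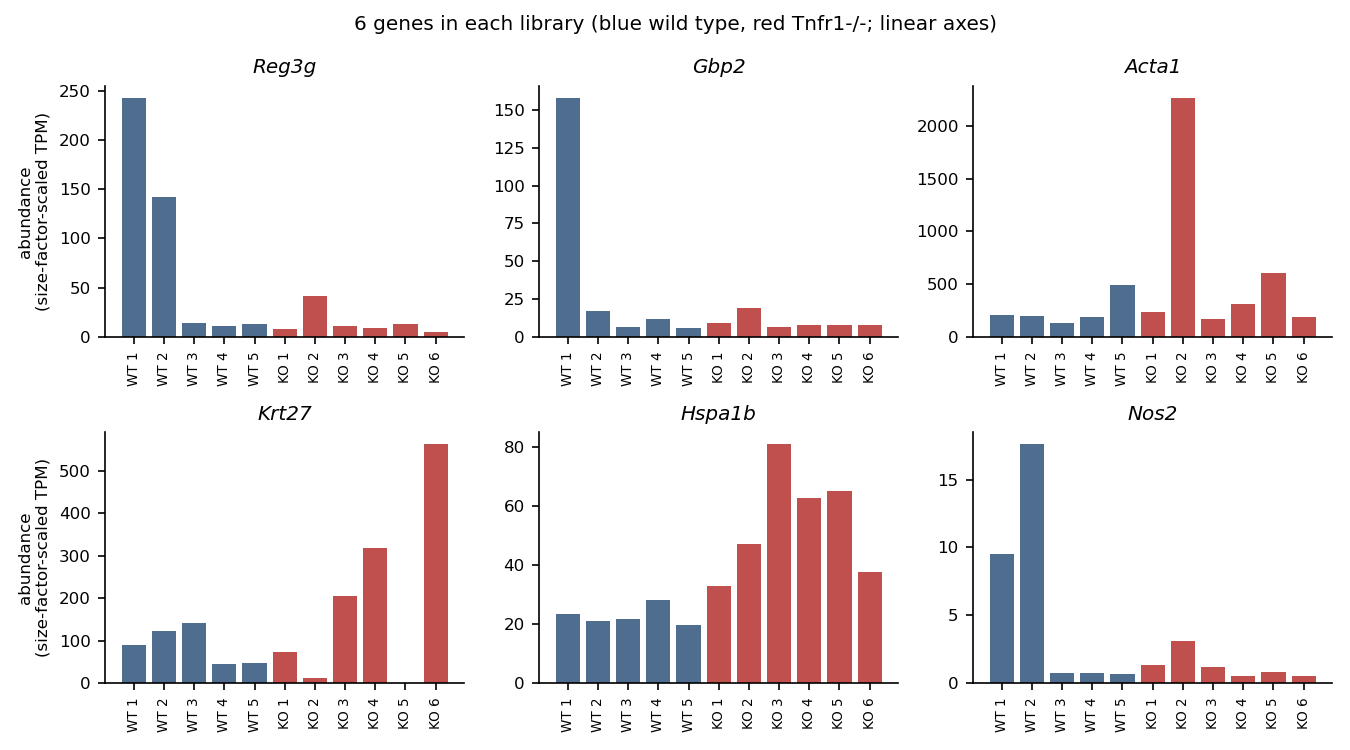
Abundance of 6 genes in each library, as bars on linear axes, with wild type in blue and Tnfr1-/- in red. Reg3g stands at 243 and 143 in wild-type replicates 1 and 2, Acta1 at 2266 in Tnfr1-/- replicate 2, and Hspa1b at 32.9 or above in all Tnfr1-/- libraries against 28 or below in wild type.

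Markers of dividing cells had the smallest exact p of any list (-0.13, exact p = 0.0887, adjusted p = 0.779). Of 30 members 29 were lower in Tnfr1-/-, 5 of them at an unadjusted p under 0.05. Cdc20, a mitotic activator, was at 28.8 ± 3.76 in wild type and 22.9 ± 1.28 in Tnfr1-/-, Ccnb2, a B-type cyclin, at 27.9 ± 2.48 and 24.3 ± 1.06, and Mcm3, a replication helicase subunit, at 31.3 ± 4.35 and 26.6 ± 2.18. Oxidative phosphorylation genes differed by -0.08 (exact p = 0.195), with 29 of 30 lower, such as Ndufa2 (223 ± 15.7 and 204 ± 6.12). Without wild-type replicates 1 and 2, the highest in that score, the difference was 0.0020.

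Among epithelial lists, stem cell and Wnt target genes did not pass as a group (-0.0078, exact p = 0.929, median log2 fold change of members 0.04). When adjusted over the list alone, 2 members were called. Cdx2, a homeobox factor of intestinal identity, was at 115 ± 11.5 in wild type and 76.2 ± 12.3 in Tnfr1-/- (log2 fold change -0.60), and Myc was at 25.4 ± 1.72 and 21.4 ± 1.44. Colonocyte genes differed by -0.09 (exact p = 0.634), with members on both sides. Scnn1b and Scnn1g, subunits of the epithelial sodium channel, were at 7.24 ± 0.918 and 5.90 ± 1.74 in wild type and 10.3 ± 1.98 and 10.5 ± 3.65 in Tnfr1-/-. Tmigd1 was at 78.9 ± 16.5 and 57.2 ± 10.9, and Guca2b, which encodes uroguanylin, at 56.8 ± 4.43 and 43.3 ± 9.55. The colonocyte score was 0.443 and 0.523 in wild-type replicates 1 and 2 and at most 0.213 elsewhere, and without those libraries the difference turned to 0.20. Enteroendocrine genes differed by -0.19 (exact p = 0.143), with 17 of 19 lower. Neurog3, the factor that starts this lineage, was at 1.28 ± 0.213 in wild type and 0.790 ± 0.235 in Tnfr1-/-, somatostatin (Sst) at 91.0 ± 25.2 and 66.0 ± 8.64, and Isl1 at 2.64 ± 0.344 and 4.27 ± 1.33.

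Genes of the suckling-to-weaning transition differed by -0.10 (exact p = 0.141), with 15 of 20 lower. When only members with a mean abundance of at least 50 were scored, the 6 left differed by -0.15 (exact p = 0.0022, the smallest the design allows, adjusted p = 0.035). It was the 1 list of 16 called under that setting.

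Macrophage and dendritic cell genes differed by -0.17 (exact p = 0.106), with 16 of 19 lower, among them the chemokine receptor Ccr2 (1.45 ± 0.334 in wild type and 1.01 ± 0.174 in Tnfr1-/-) and the Fc receptor Fcgr1 (1.93 ± 0.538 and 1.28 ± 0.336). Enteric glia genes differed by 0.06 (exact p = 0.526), although the median log2 fold change of the members was -0.07 and the difference turned to -0.077 without wild-type replicates 1 and 2.

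Immediate early and dissection stress genes differed by -0.06 (exact p = 0.693), with 5 members higher and 3 lower at an unadjusted p under 0.05. The heat shock genes Hspa1b and Hspa1a, called when adjusted over the list alone, were at 22.8 ± 3.19 and 9.45 ± 1.14 in wild type and 54.3 ± 18.3 and 23.9 ± 10.6 in Tnfr1-/-. All 6 Tnfr1-/- libraries had more Hspa1b than all 5 wild-type libraries. These 2 genes are near-identical copies, so their separate values are uncertain. Their cochaperone Dnajb1 was at 24.3 ± 0.774 and 32 ± 5.71, and Jund, an AP-1 factor, at 91.8 ± 9.92 and 78.5 ± 4.00.

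The 47 tested genes of the list next to Tnfrsf1a on chromosome 6 did not pass as a group (-0.0023, exact p = 0.939), with 5 at an unadjusted p under 0.05. Smallest in p among them was Ltbr (chromosome 6, 125306571 to 125313885), which is also in the list of TNF receptor genes and was not called when adjusted over the list alone of neighbours (adjusted p = 0.168). Foxj2 was at 9.59 ± 0.518 in wild type and 11.0 ± 0.657 in Tnfr1-/-, and Acrbp at 5.66 ± 1.07 and 7.60 ± 1.29. Within 2.5 Mb of Tnfrsf1a on either side, 6 of 57 genes (10.5%) had an unadjusted p under 0.05, against 9.38% in the genome.

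**Figure D4:**
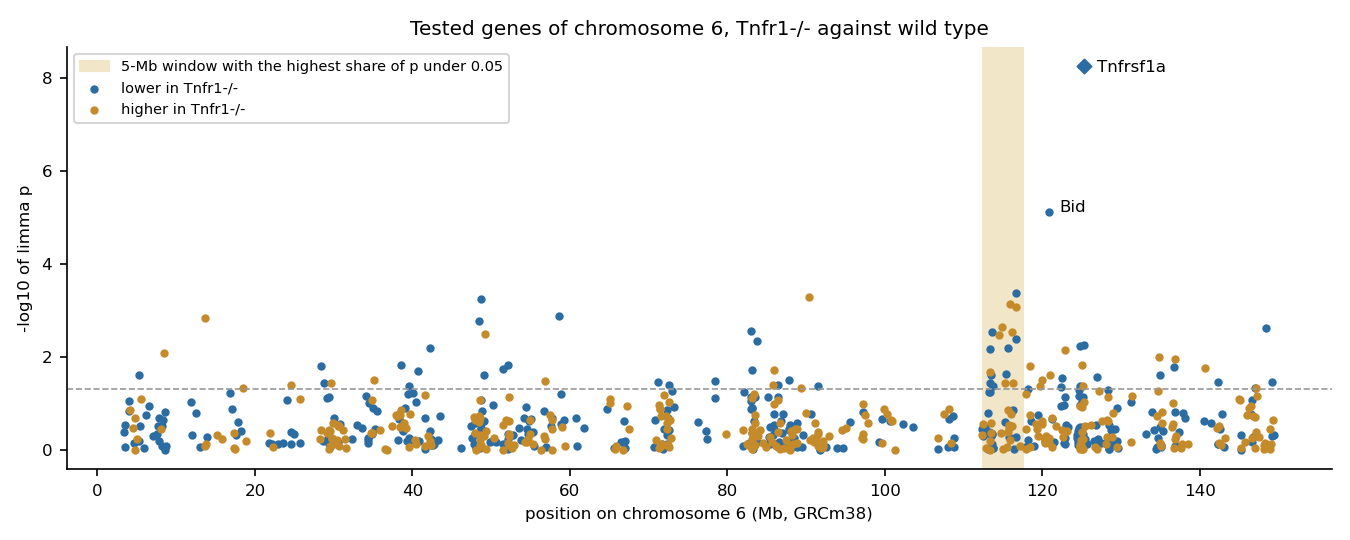
Minus log10 of the unadjusted limma p of each tested gene of chromosome 6 against its position (Mb, GRCm38), coloured by direction. Tnfrsf1a stands far above all others, Bid is next, and the shaded window from 112.5 to 117.5 Mb has 17 of 53 genes above the dashed line at 0.05.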

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

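The tests of strain DNA, of read loss, of the heat shock genes and of the antimicrobial genes were chosen after the patterns were seen, except that the bound for the Hox genes was set before their values were seen. The splits and the window scan were planned before their results were seen.

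Of 52 groups of values checked for a library far from the rest of its group, 3 had one, where chance gives about 2.6. Rbm12b2 was at 6.67 in wild-type replicate 4, below the other 4 wild-type libraries, the nearest at 7.85. Itpka was at 6.5 in Tnfr1-/- replicate 3, above the other 5, the nearest at 5.80. Hinfp was at 11.4 in Tnfr1-/- replicate 2, above the other 5, the nearest at 8.87.

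For the count of called genes, 5 of 100 splits of the libraries, the real one included, gave at least the real count of 1, with 2 the highest of the others, so chance cannot be excluded for the number of calls alone. That count does not bear on which gene was called: for Tnfrsf1a itself the real split was the most extreme of all possible ones (exact p = 0.0022, a test added after the result was seen). For transcripts, 4 of 100 splits, the real one included, gave at least the real count of 3, and the highest other gave 5. That met the bound of under 5 splits set beforehand, by no more than 1 split. As another split called more than the real one, chance is not excluded for that count. At an unadjusted p under 0.05 a typical other split had 586 genes against the real 1413, the highest had 2802, and 7 of 100 splits had as many as the real one. For transcripts at that p a typical other split had 1541 against the real 2749, the highest had 3550, and 5 of 100 splits had as many, so by this measure chance cannot be excluded. In 34 of the other splits at least 1 transcript was called.

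A window of chromosome 6, from 112.5 to 117.5 Mb and 7.85 Mb from Tnfrsf1a, held 17 of 53 genes at an unadjusted p under 0.05, the most extreme of 559 windows. Neighbouring genes that vary together by chance are a possible explanation, since 10 of 100 splits had a window with a binomial tail at least as small as the real 3.95e-06, the smallest other being 9.4e-28. Loss of reads over strain variants in Tnfr1-/- is argued against, as 9 of the 17 genes were lower and 8 higher. DNA of another strain kept beside the targeted gene cannot be told apart from chance: 10.5% of the genes within 2.5 Mb of Tnfrsf1a had such a p, a share that 36.5% of windows reach. That range leaves out Bid, 4.43 Mb from Tnfrsf1a, so for Bid such DNA was not tested. The labels give no strain, so what the flanks hold stays open.

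Hspa1a and Hspa1b were higher in Tnfr1-/-. Reads moved between the near-identical copies are argued against, since their sum was 2.42 times that of wild type (78.1 ± 28.8 and 32.2 ± 4.22) and at least 44.3 in all 6 Tnfr1-/- libraries against at most 39.3 in all 5 wild-type ones. Handling of the tissue cannot be told apart from genotype: the score of 19 other immediate early genes differed by -0.26, opposite in sign to what handling predicts, but with an exact p = 0.180. A shared heat shock response may be part of it, as 15 other heat shock genes differed by 0.15, but with an exact p = 0.0303 before and 0.0606 after adjustment over both tests. An effect of genotype and an unrecorded difference in dissection both stay open.

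Antimicrobial genes were high in wild-type replicates 1 and 2 alone. Their score exceeded that of tight junction genes by 0.838 and 0.823 in these libraries and by at most 0.327 in the other 9. Over goblet genes the excess was 0.599 and 0.612 against at most 0.458, and over colonocyte genes 0.533 and 0.539 against at most 0.129. These libraries were picked for that same score, and the goblet and colonocyte lists share genes with the antimicrobial one. The comparison therefore cannot decide whether a larger share of epithelium is the whole cause. A larger share stays open, since goblet (0.376 and 0.449) and colonocyte (0.443 and 0.523) scores were the highest of all libraries. Fibroblast (-0.360 and -0.435) and endothelial (-0.217 and -0.285) scores were the lowest. Another position along the colon stays open: the posterior Hox score was 0.0078 and -0.13, inside the range of the others from -0.26 to 0.27, but the members went both ways, with Hoxa13 at 25.2 and 27.1 above all others and Hoxd10 at 9.77 and 8.21 below all others, so the bound set on the mean score was a poor one. That loss of Tnfr1 removes a state that only some wild-type animals show cannot be told apart from chance, since the spread of the score was larger in wild type with an exact p = 0.0281 and an adjusted exact p = 0.338 over 36 lists. With 2 such animals of 5, a litter or microbial exposure that the labels do not record was not tested.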

How the results depend on the processing

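The Eif2s3y, voom, summed-identifier and principal component fits and those without a pair of libraries were chosen after the data were seen. Tnfrsf1a was called in all 25 other settings, with a log2 fold change from -1.64 to -1.51 and an adjusted p from 1.6e-06 to 0.0070. For 86 single genes and lists, 1880 of 1917 comparisons with other settings kept direction and side of the threshold, 10 passed it, 0 lost it and 27 turned direction; none of the 27 had passed. The count of called genes, 1, became 3 with sample quality weights (Bid and Ppp1r10 added), 4 with the Eif2s3y covariate (Bid, Tob2 and a predicted gene added) and 2 with principal components (Bid added). It ran from 1 to 2 as single libraries were left out, 2 without wild-type replicate 1 (Bid, adjusted p = 0.039). The count of called transcripts, 3, became 1 without Tnfr1-/- replicates 2 and 5, 5 without wild-type replicates 1 and 2, and ran from 1 to 10 as single libraries were left out. Called lists, 0, became 1 when members had a mean of at least 50, and 10 with camera's preset correlation, but stayed 0 with its estimated one. The cause was not tested.

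Among the genes and lists followed across settings, some differences turned direction without wild-type replicates 1 and 2. They were Isg15 0.013, Oas1a 0.046, NF-kB targets 0.038, TNF receptor signalling 0.060, type I interferon 0.074 and interferon-gamma 0.026. Antimicrobial 0.41, oxidative phosphorylation 0.0020, colonocytes 0.20 and enteric glia -0.077 turned as well. These 2 libraries were picked for their high antimicrobial scores. Leaving out libraries at 1 end of their group moves a difference by construction, so the turns do not bear on its cause. Some lists that were not followed also turn by their library scores. Among them are the smooth muscle, fibroblast, goblet cell, tight junction, sterol synthesis, B cell, red blood cell and interstitial cell of Cajal lists. The stem cell list was at 0.049 without Tnfr1-/- replicates 2 and 5, and the chromosome 6 neighbours at 0.0058 with members of at least 50. As single libraries were left out, differences crossed 0 for some of the followed lists. They were antimicrobial genes (-0.40 to 0.055), colonocytes (-0.18 to 0.031), chromosome 6 neighbours (-0.016 to 0.020) and immediate early genes (-0.18 to 0.046). Stem cells (-0.045 to 0.033) and, among lists added later, hair follicle (-1.07 to 0.64) crossed 0 too. By their library scores, lists not followed also cross 0 without wild-type replicate 2, among them smooth muscle, fibroblasts, goblet cells, tight junctions and B cells. The cause was not tested.

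Replicate numbers are shared between groups by name. Tnfr1-/- replicate 6 shares its number with no wild-type library, so a replicate block takes it out of the comparison. The log2 fold changes are then those without that library, such as -4.16 for ENSMUST00000131434.1. With a replicate block the fit called 1 gene, Tnfrsf1a, and 2 transcripts, both of Tnfrsf1a (ENSMUST00000032491.14 and ENSMUST00000131434.1), but not those of Midn and Bahcc1. It called 0 lists; the smallest p that 32 sign flips can give is 0.0625, and 3 lists were at it (enteroendocrine and small intestine lower, circadian clock higher). Of 5 Tnfr1-/- libraries 1 correlated best with the wild-type library of its own number, so the numbers are not read as pairs. DESeq2 was not run, since the values are not counts, and neither was the planned Xist covariate. Transcripts near an abundance of 1 rest on few reads at these depths.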

Other observations

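The muscle, skin and heat shock lists described here and their tests by sex were chosen after the data were seen, as were the genes named. Markers of skeletal muscle and of skin varied widely among libraries. Acta1, the actin of skeletal muscle, was at 2266 in Tnfr1-/- replicate 2, 605 in Tnfr1-/- replicate 5 and 485 in wild-type replicate 5, and between 128 and 305 in the other 8 libraries. These are 3 of the 4 libraries with Eif2s3y above 10, and in the fourth, wild-type replicate 2, Acta1 was at 195. The muscle creatine kinase Ckm was at 1566 in Tnfr1-/- replicate 2. Krt27, a keratin of the hair follicle, was at 563 in Tnfr1-/- replicate 6 and 0.322 in Tnfr1-/- replicate 5, and Krt5, a keratin of stratified epithelium, at 249 and 19.2. By genotype, scores differed by 0.75 for 22 skeletal muscle genes (exact p = 0.409), -0.41 for 23 hair follicle genes (exact p = 0.805) and 0.50 for 23 stratified squamous genes (exact p = 0.238). Without Tnfr1-/- replicate 2 the muscle difference was 0.19. Without Tnfr1-/- replicate 5 the hair follicle difference turned to 0.64 and the squamous one was 0.81 (adjusted exact p = 0.032). The squamous list did not pass when any other single library was left out. For 20 heat shock genes, which include Hspa1a and Hspa1b, the difference was 0.29 (exact p = 0.0152, adjusted p = 0.061 over the 4 lists). It passed without Tnfr1-/- replicate 5 (adjusted exact p = 0.048) or wild-type replicate 1 (adjusted exact p = 0.038). With any other single library left out it did not pass (adjusted exact p from 0.063 to 0.114). Between the 4 libraries with Eif2s3y above 10 and the other 7, scores differed by 2.04 for skeletal muscle (exact p = 0.0121, adjusted exact p = 0.048 over the same 4 lists), -2.98 for hair follicle (exact p = 0.0303, adjusted exact p = 0.061), -0.50 for stratified squamous (exact p = 0.255) and -0.0025 for heat shock genes (exact p = 0.994). The first principal component of all tested genes held 41.9% of the variance and the second 17.5%. The first was lowest in Tnfr1-/- replicate 5 (-60.4) and highest in Tnfr1-/- replicate 6 (42.5). The hair follicle score was -5.46 and 3.07 in these libraries. That component ordered the libraries as the hair follicle score did, except that wild-type replicates 4 and 5 changed places. The source of this variance was not tested. Whether it lowered the power to detect differences by genotype was not tested either.

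Interferon-inducible genes were at their highest in 1 animal. Gbp2, a guanylate-binding GTPase, was at 158 in wild-type replicate 1 and between 5.76 and 18.7 in the other 10 libraries, and Iigp1 was at 78.4 against 2.12 to 9.53. The inducible nitric oxide synthase Nos2 was at 9.54 in wild-type replicate 1 and 17.6 in replicate 2, against 0.531 to 3.11 elsewhere. The score of 10 B cell and follicle genes was 1.42 in wild-type replicate 2 and at most 0.578 in the other 10 libraries. Lists of smooth muscle (0.10, exact p = 0.604), fibroblasts (0.08, exact p = 0.623), goblet cells (-0.07, exact p = 0.688) and enteric neurons (-0.21, exact p = 0.353) did not pass between genotypes. Wild-type replicate 2 was at -0.559 for smooth muscle, -0.435 for fibroblasts and 0.449 for goblet cells. By the library scores, the difference of each of these lists turns direction without that library. For enteric neurons 23 of 23 members were lower in Tnfr1-/-, with 0 at an unadjusted limma p under 0.05. The wild-type libraries were far apart in that score, at -0.262, -0.493, 0.535, 0.640 and 0.164 in replicates 1 to 5. The Tnfr1-/- mean was -0.097.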
